A study of Mus musculus with 5 samples.

How the data were processed

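Total RNA from whole uterus was measured on 5 Affymetrix mouse genome arrays, 1 for each of 5 pools of uterine horns. Per the labels, RNA preparation, cRNA labelling and hybridisation followed the manufacturer's recommendations. The software that made the values and the kind of normalization were not given in the sources used here. The deposited values were taken as log2, although the labels do not state the base. Read as natural logs, between 1.14% and 1.61% of the values of each array would have exceeded the range of a 16-bit scanner, so base 2 was used. Low values had been raised to a common minimum of 5.39 (42.0 in linear units) before deposition, and between 19.9% and 21.3% of the probe sets of each array lay at it. The 0 h, 1 h, 3 h, 6 h and 9 h arrays held 18, 31, 30, 14 and 42 empty cells, and a comparison left out a probe set that was empty on either of its arrays.

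The table held 12487 probe sets, of which 65 were Affymetrix control probe sets and were left out of the comparisons. Gene symbols came from the platform's probe table. Of the 12422 remaining probe sets, 10833 carried 1 symbol, 396 carried several and 1193 carried none. The Entrez identifiers of 10817 of the first group were found in the mouse gene reference, which changed 0 symbols. Where a value per gene was needed, the probe set with the highest mean over the 5 arrays was taken, which gave 8251 genes.

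Values were converted to linear units and divided by the mean of each array after trimming 2% at each end, then multiplied by the mean of the 5 trimmed means. The trimmed means ran from 237 to 268 and the resulting scaling factors from 0.950 to 1.07. A floor was set at the 40th percentile of the scaled values (99.5, or 6.64 on the log2 scale), and lower values were raised to it before differences were taken on the log2 scale. In all, 6666 probe sets lay above the floor on all 5 arrays and 4209 lay at or below it on all 5. A probe set counted as at least 2-fold higher or lower when its log2 difference was 1 or more in size and the higher of the 2 values was at least 2 times the floor (199). Where the lower value was at the floor, the fold is a lower bound. With 1 array per time no test between groups was possible, so each difference describes a pair of arrays and carries no error or p-value, and the number of arrays limits the precision.

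The 1 h, 3 h, 6 h and 9 h arrays were each compared with the uninjected 0 h array, and each later array with the one before it. Probe sets were also sorted by the times at which they passed: at all 4 times, at 1 h or 3 h with under 1.5-fold in the same direction at 6 h and 9 h, and at 6 h and 9 h with under 1.5-fold in the same direction at 1 h and 3 h. The plan did not say whether the 1.5-fold limit held in both directions, so a limit in either direction was also counted. A total of 17 gene lists and 13 lists of cell type or tissue markers were fixed before the data were examined. The gene lists were progesterone receptor targets, oestrogen-responsive uterine genes, immediate early genes, glucocorticoid and stress hormone targets, circadian clock genes, cell cycle and DNA replication, heat shock and protein folding, endoplasmic reticulum stress and chaperones, cholesterol synthesis and uptake, steroid receptors and cofactors, steroid and retinoid metabolism, hedgehog, Wnt and BMP signalling, interferon-stimulated genes, cytokines, chemokines and prostaglandin synthesis, extracellular matrix and remodelling, the insulin-like growth factor system and growth factors, and ribosomal proteins. The marker lists covered epithelium, endometrial stroma and fibroblasts, smooth muscle, endothelium, macrophages and dendritic cells, lymphocytes and plasma cells, neutrophils, mast cells and eosinophils, erythrocytes, adipose tissue, skeletal muscle, ovary and oviduct, and nerve and Schwann cells. A list member counted as measured when it was at the floor or above it on at least 1 array of the pair. The median log2 difference of the measured members was set against 10000 random lists of the same size, matched in 10 bins of expression, and was called above or below the random range when it lay outside the central 95% of them. With 30 lists, 1.5 were expected outside by chance at each time. Genes within a list are not independent of one another, so the range shows only how a list lay against other genes on the same arrays.

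Genes named in the text followed a rule fixed before the data were examined. At each time it took the 8 largest differences in each direction among genes above the floor on both arrays with the higher value at least 4 times the floor (398), and the 3 largest lower bounds in each direction. For the consecutive comparisons it took the 3 largest in each direction. From each list it took up to 4 measured members with the largest difference at the time when the list's median lay furthest out, and it took Pgr and Esr1 at all times. Other probe sets of a named gene were checked for direction. A few further genes stand in counts of the timing groups or beside a list, and were chosen after their values were seen.

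The calls were tested on simulated data built from the spread between the 6 h and 9 h arrays. In 20 simulations of 12293 probe sets, 200 probe sets with a mean of at least 4 times the floor were changed. Of the changes, 689 of 1340 of 2-fold (51.4%), 1311 of 1340 of 3-fold (97.8%) and 1316 of 1320 of 4-fold (99.7%) were recovered. Recovery in probe sets with lower means was not tested, although the rule for a call starts at 2 times the floor. A mean of 17.7 calls fell among 12093 unchanged probe sets. Of 40 unshifted lists of 20 genes, 39 lay inside the random range, and 40 of 40 lists shifted by 0.5 lay above it. The unshifted lists were drawn at random like the reference lists, so they do not test lists of genes that vary together. All 4 differences from 0 h share 1 array, so the overlap between times was set against 100 simulations with no effect.

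The alternatives tried were the values as deposited without scaling, quantile normalization, centring on the median of the probe sets above the floor, floors at the 25th and 55th percentiles, a pseudocount equal to the floor, a 3-fold limit, no minimum on the higher value, 1 probe set per gene, and the mean over the probe sets of a gene. Use of the 1 h array as the baseline and the 1.5-fold limit in either direction were added after the data were seen. Without scaling, the median difference of the probe sets above the floor on all arrays was -0.12 at 1 h, -0.13 at 3 h, -0.04 at 6 h and 0.02 at 9 h, against 0.03, 0.05, 0.03 and 0.02 with the scaling used. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. No genome coordinates are given, because the files name no genome build.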

Results

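Gene expression was profiled in the uterus of female wild-type 129/SvImJ mice, an inbred strain, aged 10 to 16 weeks, whose ovaries had been removed 14 days earlier. Removal of the ovaries takes away the main source of oestrogen and progesterone. Mice received 0.2 mg progesterone in 0.1 mL sesame oil under the skin, and uterine horns were collected 1 h, 3 h, 6 h or 9 h later. A control pool came from uninjected mice and is called 0 h. Each pool held 8 uterine horns from 4 mice and was measured on 1 array, so there are 5 arrays and no replicates. The series holds no array from mice given oil alone and none from uninjected mice at later times, so hormone, oil, handling and time of day were not separable. The differences below were not tested and describe pairs of arrays. They are on the log2 scale unless a fold or a scaled value is named, and all scaled values are in linear units.

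The 5 arrays were alike in their overall levels. Median deposited values lay between 7.11 and 7.17, and between 58.5% and 61.8% of probe sets were above the floor. Across probe sets, the correlation of log2 values between arrays ran from 0.956 (1 h and 9 h) to 0.985 (6 h and 9 h), and probe sets are not independent replicates. Among 4241 probe sets at 2 times the floor or more on all arrays, 95% differed from 0 h by less than 1.52-fold at 1 h, 1.70-fold at 3 h, 1.64-fold at 6 h and 1.79-fold at 9 h. These figures hold array error, differences between pools and response together.

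The comparison of 1 h with 0 h asked which uterine genes differed soonest after progesterone. Sgk1, a kinase induced by steroid hormones, was 3.55-fold higher (scaled value 282 at 0 h and 1003 at 1 h), and Hsph1, a cytosolic chaperone, was 3.00-fold higher. Myc, a growth-promoting transcription factor, was 2.65-fold higher, Gadd45g, a stress-response gene, 2.33-fold higher, and Zbtb16, a zinc finger transcriptional repressor, 2.17-fold higher, with a difference of 0.39 at its other probe set. Tiparp, an ADP-ribosyltransferase known as a target of the aryl hydrocarbon receptor, was at the floor at 0 h and at least 6.58-fold higher at 1 h. Lower values were led by Ovgp1, an oviductal glycoprotein (3.46-fold, from 753 to 218), and Acta1, skeletal muscle actin (2.69-fold).

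In all, 62 probe sets were at least 2-fold different at 1 h, 40 higher and 22 lower. Further genes with higher values were Errfi1, a feedback inhibitor of epidermal growth factor receptors (830 and 1963, a difference of 1.24, with 1.80 at its other probe set), the activin-binding Fst (at least 2.64-fold), the DNA damage checkpoint gene Hus1 (at least 2.27-fold, with a difference of 0.05 at its other probe set) and the antibody light chain gene Igkv9-120 (2.73-fold). Of the receptor genes, Esr1, the oestrogen receptor, was 2.51-fold higher at 1 probe set, with differences of 0.21 to 0.62 at its 3 other probe sets. Pgr, the progesterone receptor, differed by 0.37, within the 1.52-fold that held 95% of probe sets. The genes with lower values included the clock output factor Dbp (-1.28), the early response gene Ier3 (-1.26), the epithelial transcription factor Elf3 (-1.11), the hemidesmosome integrin Itgb4 (-1.11), the fat hormone Adipoq (-1.07) and Efnb2, a ligand of Eph receptors (-1.04).

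Known progesterone receptor targets were above the random range at 1 h, with a median of 0.36 and 5 of 28 measured members at least 2-fold higher and 0 lower, namely Sgk1, Myc, Fst, Errfi1 and Zbtb16. Glucocorticoid and stress hormone targets, which share 8 genes with that list, had a median of 0.39 with 5 of 28 higher, namely Sgk1, Errfi1, Zbtb16, the transcriptional repressor Bcl6 (1.12) and Pdk4 (1.07), a kinase that inhibits pyruvate dehydrogenase. The immediate early genes had a median of 0.17 with 2 of 31 higher, Myc and Gadd45g, and 2 lower, Ier3 and Gadd45b (-1.02, with -0.15 at its other probe set), but this median lay inside the random range under 5 of 7 other settings (0.11 to 0.12). Above the range too were heat shock and protein folding genes (0.33, 1 of 15 higher, Hsph1), ribosomal proteins (0.16, 0 of 14) and markers of endometrial stroma and fibroblasts (0.16, 0 of 16, with Mfap4 at 0.77, Thy1 at -0.56 and Col3a1 at 0.48). Ribosomal proteins lay inside it with quantile normalization (0.0021) and with a floor at the 25th percentile (0.15), and stroma markers with the mean over probe sets (0.10).

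Interferon-stimulated genes were below the random range at 1 h, with a median of -0.45 and 2 of 19 at least 2-fold lower. They were Psmb9 (-1.13), a subunit of the immunoproteasome, and Irf7 (-1.06, with -0.37 at its other probe set), a transcription factor of the interferon response. Epithelium markers had a median of -0.40 with 1 of 17 lower (Elf3), adipose tissue markers -0.43 with 1 of 8 lower (Adipoq), and markers of macrophages and dendritic cells -0.31 with 0 of 13. Genes of cholesterol synthesis and uptake had a median of -0.24 with 0 of 14, and their lowest members were Hmgcs1 (at least 0.91 lower on the log2 scale), Scd1 (-0.51), Fdps (-0.49) and Ebp (-0.43). Cell cycle and DNA replication genes stayed inside the range (median 0.17), with 0 of 21 at least 2-fold different and values of 0.52 for Lig1, 0.51 for Ttk, 0.46 for Ccna2 and -0.42 for Stmn1. Of the 30 lists, 6 were above and 5 below the range. The balance of directions at 1 h depended on the scaling: without it 24 probe sets were higher and 50 lower, and with median centring 31 were higher and 30 lower. A pseudocount in place of the floor left 18 probe sets, a floor at the 55th percentile 36, 1 probe set per gene 41 and a 3-fold limit 6.

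**Figure D1:**
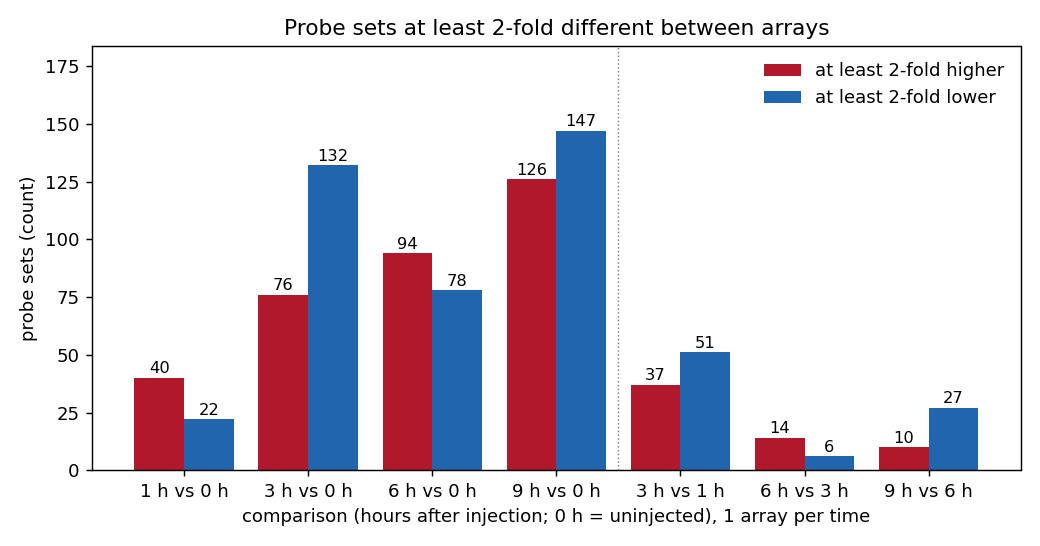
Number of probe sets (vertical axis) at least 2-fold higher or lower in each comparison (horizontal axis), 1 array per time. Against the uninjected array 62 probe sets passed at 1 h, 208 at 3 h, 172 at 6 h and 273 at 9 h.

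The comparison of 3 h with 0 h asked which genes differed next. Acot7, an acyl-CoA thioesterase, was 13.5-fold higher (107 and 1446), Mthfd2, a mitochondrial folate enzyme, 7.03-fold higher (117 and 823), Pdk3, a kinase that inhibits pyruvate dehydrogenase, 4.50-fold higher, and Lrp2, the endocytic receptor megalin, 4.39-fold higher (111 and 488). The 0 h values of Acot7, Mthfd2 and Lrp2 lay near the floor. With a pseudocount their differences of 3.75, 2.81 and 2.13 became 2.90, 2.09 and 1.48. Zbtb16 was 5.39-fold higher, Fkbp5, a co-chaperone of steroid receptors, 4.09-fold higher, and Npl, which splits sialic acid, at least 8.92-fold higher. Among the lower genes, Adipoq was 4.62-fold lower, Scd1, a fatty acid desaturase, 4.47-fold lower and Ltf, the secreted protein lactoferrin, 3.28-fold lower (886 and 271).

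A total of 208 probe sets were at least 2-fold different at 3 h, 76 higher and 132 lower. Also among the highest were Myd88, an adaptor of Toll-like receptors (4.22-fold), Sgk1 (3.86-fold), Cyp26a1, which degrades retinoic acid (at least 5.48-fold), and Fst (at least 4.14-fold). The other probe set of Zbtb16 differed by 0.68. The lowest also included Emb, a cell surface glycoprotein (4.14-fold), Ovgp1 (-1.96), Car3, a carbonic anhydrase abundant in fat and muscle (3.85-fold, 1838 and 478), the antibody light chain gene Igkv4-68 (-1.86), Efnb2 (3.61-fold) and Eya2, a transcriptional coactivator (3.36-fold). At or below the floor at 3 h were the tetraspanin Tspan8 (at least 4.16-fold lower), the lymphocyte phosphatase Ptpn22 (at least 3.52-fold) and Igkv6-14 (at least 3.47-fold). Pgr differed by 0.00 and Esr1 by 0.66, with only 1 of the 3 other Esr1 probe sets in the same direction.

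Progesterone receptor targets had a median of 0.60 at 3 h, with 10 of 28 members at least 2-fold higher and 1 lower. The higher ones included Ihh, a hedgehog ligand made by uterine epithelium (1.72), and Hdc, which makes histamine (1.60), and the lower one was Lifr, the receptor for leukaemia inhibitory factor (-1.22). Extracellular matrix genes had a median of 0.29 with 1 of 33 higher, the collagen gene Col5a2 (1.00), and values of 0.67 for Col1a1, 0.61 for Col3a1 (0.05 to 0.45 at its other probe sets) and 0.59 for Thbs2. Above the range as well were glucocorticoid targets (0.22, 3 of 27 higher, namely Fkbp5, Sgk1 and Zbtb16), endoplasmic reticulum chaperones (0.28, 0 of 16), steroid receptors and cofactors (0.26, 1 of 14, Fkbp5), stroma markers, which share 7 genes with the extracellular matrix list (0.19, 1 of 17, Hoxa11) and skeletal muscle markers (0.44, 1 of 8). The skeletal muscle member was Acta1, with lesser differences for Tnnc2 (at least 0.57), Mylpf (0.53) and Casq1 (0.46). Under 5 of 7 other settings the steroid receptor median lay inside the range (0.13 to 0.19). Skeletal muscle did so with a floor at the 25th percentile (0.36), glucocorticoid targets with quantile normalization (0.16), and skeletal muscle (0.24) and chaperones (0.19) with the mean over probe sets.

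Marker lists of several cell types were below the random range at 3 h. Epithelium markers had a median of -0.58 with 2 of 17 at least 2-fold lower, the adhesion molecule Epcam (at least 2.67-fold) and the keratin Krt18 (2.48-fold, 1409 and 569), and values of -0.85 for Krt7 and -0.76 for Krt19. Adipose tissue markers had a median of -0.64 with 3 of 8 lower, Adipoq, Car3 and Lpl (-1.67), and Retn differed by -0.71. For lymphocytes and plasma cells the median was -0.45 with 2 of 7 lower, the antibody genes Ighm (-1.36) and Jchain (-1.34), and for macrophages and dendritic cells -0.41 with 0 of 13. Erythrocyte markers had a median of -0.68 with 2 of 4 lower, the haemoglobin genes Hbb-b2 (-1.53) and Hba-a1 (-1.13). Interferon-stimulated genes had a median of -0.54 with 2 of 19 lower, the immunoproteasome genes Psmb8 (-1.35) and Psmb9 (at least 1.27 lower). Lymphocytes and plasma cells lay inside the range with a floor at the 25th percentile (-0.10) and with the mean over probe sets (-0.18), as did macrophages and dendritic cells with that mean (-0.20). Of the 30 lists, 7 were above and 6 below the range. Without scaling, 44 probe sets were higher and 200 lower at 3 h, and a pseudocount left 103 probe sets and a 3-fold limit 46. With the 1 h array as the baseline 88 probe sets passed. Progesterone receptor targets then had a median of 0.24, still above their range, and glucocorticoid targets one of -0.14, while chaperones (0.078), steroid receptors (0.030), stroma (0.021), macrophages (-0.035) and lymphocytes (-0.11) were inside their ranges. Lists that lay outside with that baseline, but not against 0 h, were oestrogen-responsive genes (-0.16), heat shock (-0.15), clock (0.13), steroid and retinoid metabolism (0.13) and hedgehog, Wnt and BMP genes (0.12).

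**Figure D2:**
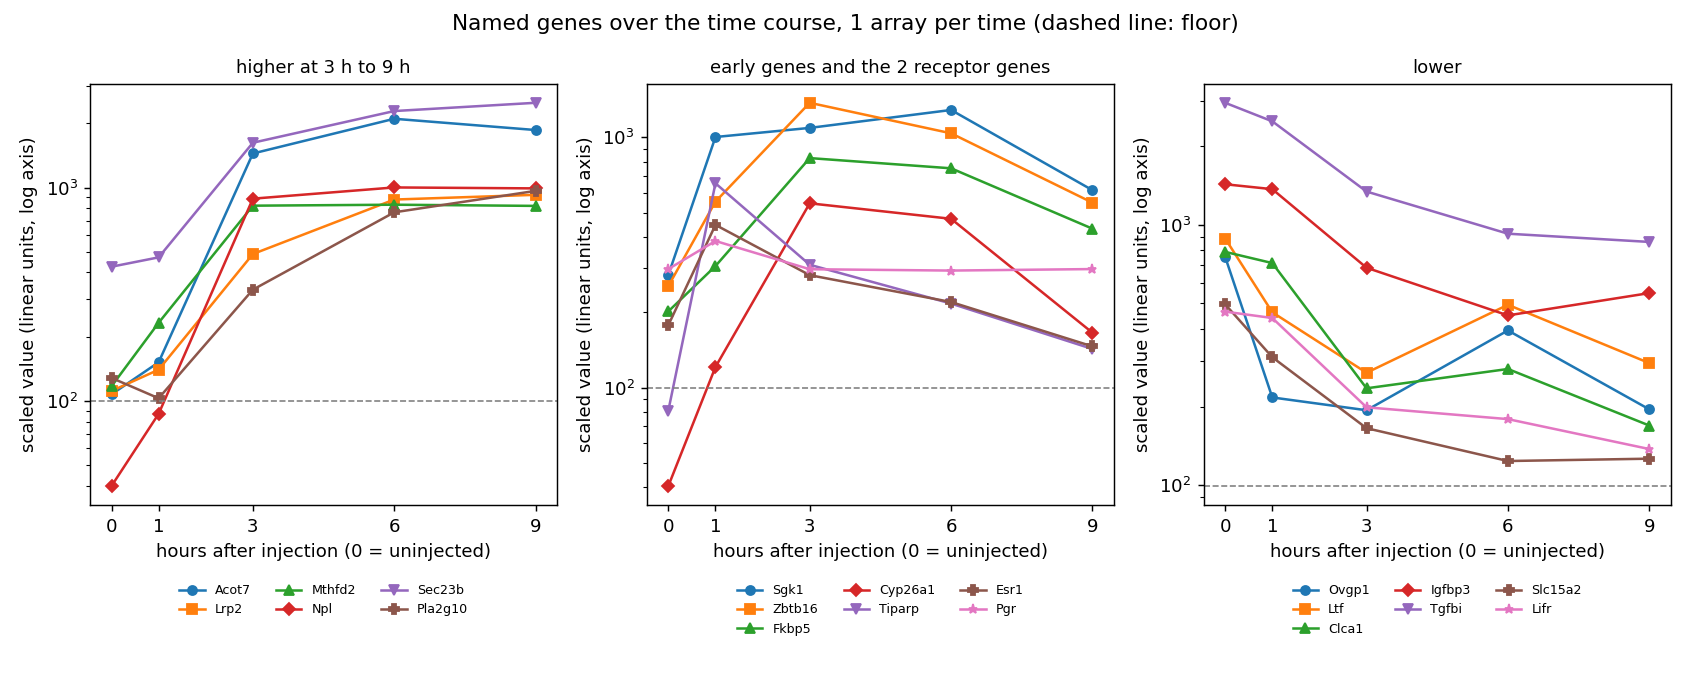
Scaled values (log axis, linear units) of named genes against hours after injection, each point 1 array and the dashed line the floor of 99.5. Acot7 ran from 107 at 0 h to 2103 at 6 h, Zbtb16 was highest at 3 h (1373), and Tgfbi ran from 2941 at 0 h to 860 at 9 h.

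The 6 h comparison with the uninjected pool asked which differences lasted or first appeared by mid-course. Genes already higher at 3 h were among the highest again. Acot7 was 19.6-fold higher (107 and 2103), Lrp2 7.90-fold, Mthfd2 7.10-fold, Pla2g10, a secreted phospholipase, 5.98-fold (128 and 766), and Npl at least 10.1-fold. The 0 h value of Acot7 lay just above the floor, and its difference of 4.29 became 3.41 with a pseudocount and 3.64 with a floor at the 55th percentile. Lrp2 (111), Mthfd2 (117) and Pla2g10 (128) lay near the floor at 0 h too. With a pseudocount their differences of 2.98, 2.83 and 2.58 became 2.22, 2.10 and 1.93. Sec23b, part of the coat of vesicles that leave the endoplasmic reticulum, was 5.37-fold higher, although its other probe set differed by 0.34. The lowest were Slc15a2, a peptide transporter (4.00-fold), Tgif1, a homeobox repressor (3.33-fold), and genes for the secreted proteins Igfbp3 (3.19-fold, 1432 and 449) and Tgfbi (3.18-fold, 2941 and 925). With the mean over its probe sets the Tgfbi difference of -1.67 became -0.83, under 2-fold. That mean counts a probe set at the floor on both arrays as 0, so the smaller value does not by itself show a contrary probe set.

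At 6 h 172 probe sets were at least 2-fold different, 94 higher and 78 lower. Others in the higher group were Myd88 (5.15-fold), Sgk1 (4.56-fold), Pdk3 (4.54-fold), Cyp26a1 (at least 4.75-fold) and the death receptor gene Tnfrsf21 (at least 2.73-fold). Also lower were Tspan8 (3.26-fold), the carbonic anhydrase Car2 (2.95-fold, 1167 and 395), Itgb4 (-1.53), the gap junction gene Gjb2 (at least 2.14-fold), Nsg2 (at least 2.81-fold) and Pon2 (at least 2.06-fold). Capg, an actin-capping protein, was lower by its main probe set (-1.50), while its other probe sets gave -1.34 and 0.19. The second Igfbp3 probe set differed by -0.84. Pgr differed by -0.02 and Esr1 by 0.31.

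Progesterone receptor targets had their largest median at 6 h, 0.67, with 12 of 31 members at least 2-fold higher and 2 lower. The higher ones included Lrp2, Sgk1, Zbtb16 (2.03) and Hdc (1.76), and the lower ones were Lifr (-1.37) and Cdkn1c (1328 and 662), an inhibitor of cell division. Heat shock genes had a median of 0.41 with 1 of 15 higher, Hsph1 (3.26-fold), and values of 0.78 for Hspa1a, 0.72 for Hspd1 (0.18 at its other probe set) and 0.61 for Hspa1b. Endoplasmic reticulum chaperones had a median of 0.35 with 2 of 16 higher, Creld2 (2.76-fold) and Hspa5 (2.17-fold, 914 and 1983), and values of 0.86 for Atf4 and 0.84 for Pdia4. Steroid receptors and cofactors had a median of 0.21 with 1 of 14 higher, Fkbp5 (1.90), and a value of 0.60 for Hsp90aa1. Glucocorticoid targets had a median of 0.20 with 4 of 27 higher, namely Fkbp5, Sgk1, Zbtb16 and Errfi1. The steroid receptor median lay inside the range under 3 of 7 other settings (0.16 to 0.21), and the glucocorticoid median with a floor at the 25th percentile (0.13). Steroid and retinoid metabolism genes stayed inside the range (0.10), with Cyp26a1 the 1 of 16 at least 2-fold higher, and values of 0.87 for Hsd11b2, which inactivates glucocorticoids, 0.85 for the retinol transporter Stra6 and 0.80 for Aldh1a2, which makes retinoic acid.

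Interferon-stimulated genes had a median of -0.56 at 6 h with 2 of 19 lower (Psmb9 and Gbp2), epithelium markers -0.52 with 1 of 17 (Epcam), adipose tissue markers -0.37 with 1 of 8 (Adipoq), and markers of macrophages and dendritic cells -0.21 with 0 of 13. For lymphocytes and plasma cells the median was -0.54 with 0 of 7 at least 2-fold different, from Thy1 (-0.76), Jchain (-0.69), Ms4a1 (-0.63, with -0.094 at its other probe set) and Ighm (-0.54), and 6 of the 7 other Ighm probe sets had the same direction. Genes of the insulin-like growth factor system and growth factors had a median of -0.17 with 1 of 27 higher (Igf1, 1.79) and 1 lower (Igfbp3). Endothelium markers stayed inside the range (-0.14), with -0.52 for Vwf and 0.06 at its other probe set, as did nerve and Schwann cell markers (0.18), with -0.45 for Prph and 0.28 for Pmp22. The lymphocyte median lay inside the range with a floor at the 25th percentile (-0.034) and with the mean over probe sets (-0.13), and that of macrophages with quantile normalization (-0.18) and with that mean (-0.10). Of the 30 lists, 5 were above and 6 below the range. Without scaling 86 probe sets were higher and 99 lower at 6 h, and with median centring 89 were higher and 89 lower. A pseudocount left 87 probe sets at 6 h and a 3-fold limit 34. With the 1 h array as the baseline 106 probe sets were higher and 63 lower, and progesterone receptor targets had a median of 0.36, above their range. The median of glucocorticoid targets was then -0.14 and that of macrophages and dendritic cells 0.057, on the other side of 0 in both cases and inside their ranges. Also inside with that baseline were the interferon (-0.15), epithelium (-0.14), lymphocyte (-0.20), adipose tissue (-0.039), heat shock (0.022) and steroid receptor (0.065) medians, while that of stroma (-0.22) lay below its range.

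**Figure D3:**
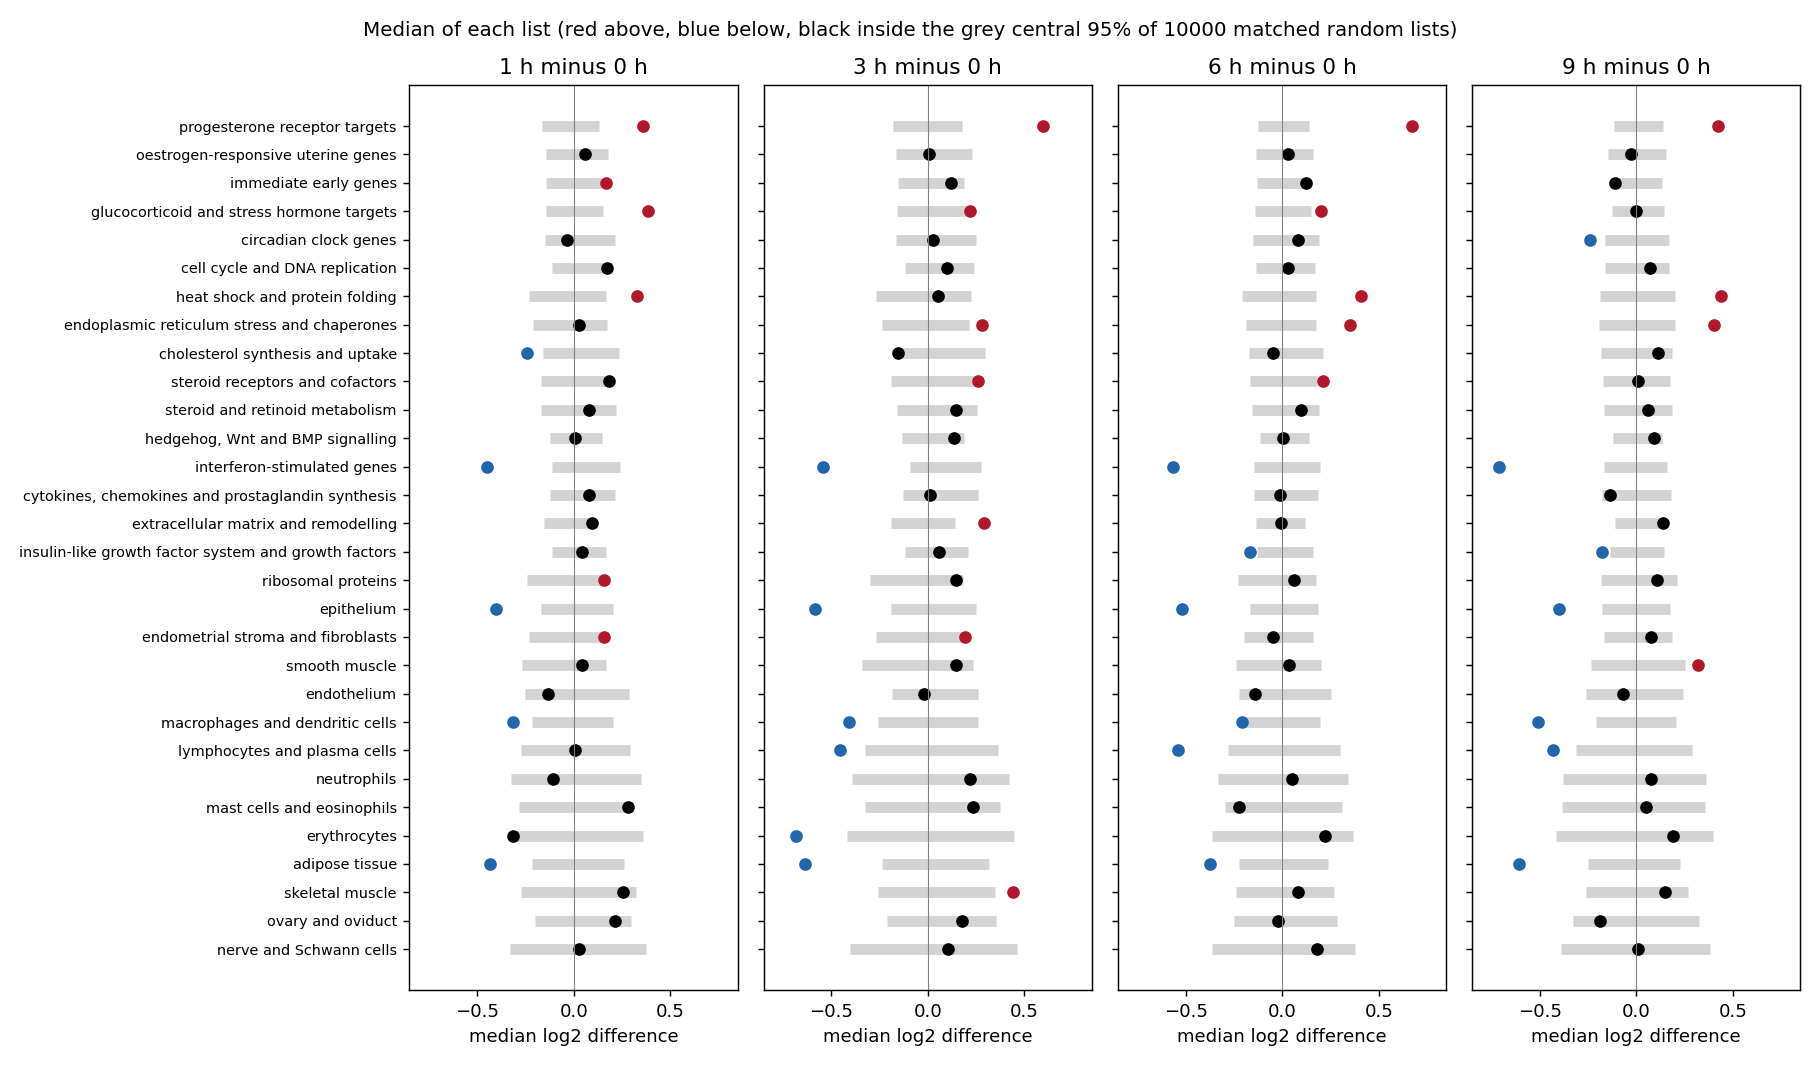
Median log2 difference from 0 h (horizontal axis) of the measured members of 30 fixed lists (vertical axis) at 4 times, with grey bars for the central 95% of 10000 matched random lists. Progesterone receptor targets had medians of 0.36, 0.60, 0.67 and 0.42 at 1 h, 3 h, 6 h and 9 h, and interferon-stimulated genes -0.45, -0.54, -0.56 and -0.71.

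The comparison of 9 h with 0 h asked which genes differed at the end of the course. Several genes that led at 6 h were again among the highest. Acot7 was 17.4-fold higher, Lrp2 8.32-fold (111 and 925), Pla2g10 7.53-fold, Mthfd2 7.01-fold and Atp1b1, a subunit of the sodium pump, 4.71-fold (196 and 922). With a pseudocount the differences of Lrp2, Pla2g10 and Mthfd2, whose 0 h values lay near the floor, went from 3.06, 2.91 and 2.81 to 2.28, 2.23 and 2.09. Among the lower genes were clock factors, with Nr1d2 4.57-fold lower (737 and 161) and Dbp at least 6.57-fold lower (653 at 0 h), and Clca1, a secreted epithelial protein, 4.64-fold lower (787 and 170). The chaperone gene Hspa5 was 3.05-fold higher (914 and 2783).

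At 9 h 273 probe sets were at least 2-fold different, 126 higher and 147 lower. Higher genes also included Sec23b (5.87-fold, with a difference of 0.35 at its other probe set), Gstm2, a glutathione transferase (4.72-fold, with 0.16 at its other probe set), Acta1 (4.61-fold, 498 and 2293), Npl (at least 9.97-fold), Tnfrsf21 (at least 3.64-fold) and Acod1, which makes itaconate (at least 3.53-fold). Lower genes also included Adipoq (-2.24), Car3 (-2.13), Igkv4-68 (-2.07), the glutathione transferase Gstt2 (4.11-fold), Slc15a2 (3.91-fold), Scd1 (3.89-fold), Igkv6-14 (at least 3.47-fold) and the glycolytic enzyme gene Aldoc (at least 3.38-fold). Pgr differed by 0.00, and Esr1 by -0.28 with 2 of its 3 other probe sets in the same direction.

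Progesterone receptor targets had a median of 0.42 at 9 h, with 7 of 31 at least 2-fold higher and 2 lower, Lifr and the lipoxygenase gene Alox15 (-1.15). Endoplasmic reticulum chaperones had a median of 0.40 with 5 of 15 higher and 0 lower, namely Creld2 (2.09), Hspa5 (1.61), Pdia4 (1.56), Pdia6 (1.51) and Hsp90b1 (1.13). Heat shock genes had a median of 0.44 with 2 of 15 higher, Hsph1 (1.80) and the collagen chaperone Serpinh1 (1.06). Smooth muscle markers were above the range (0.32) with 0 of 10 at least 2-fold different, and values of 0.61 for Tpm2, 0.47 for Acta2, 0.47 for Tpm1 and 0.40 for Mylk, but the median lay inside the range with a floor at the 55th percentile (0.29). Extracellular matrix genes were inside the range (0.14), although above it with a floor at the 25th percentile (0.14) and with the mean over probe sets (0.15), with 4 of 33 at least 2-fold higher, the collagen genes Col15a1 (1.56), Col1a1 (1.34), Col6a3 (1.22) and Col6a2 (1.20). Hedgehog, Wnt and BMP genes were inside the range against 0 h at all 4 times (0.09 at 9 h, 1 of 30 higher, with 2 of 31 higher at 3 h, Ihh and Fzd1, and 4 of 31 at 6 h, those and Wnt11 and Id1), although Ihh was 2.65-fold higher, Gli1, a target of hedgehog signalling, was 0.94 higher, and Wnt11 and Dkk3 differed by 0.83 and -0.83.

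Circadian clock genes were below the random range at 9 h and inside it at the earlier times, with a median of -0.24 and 5 of 19 at least 2-fold lower and 1 higher. Dbp, Nr1d2, Tef (-1.41), Rora (-1.07) and Nr1d1 (-1.03) were lower, and Arntl, whose product drives the clock's output genes, was 2.13-fold higher (137 and 293). The insulin-like growth factor list had a median of -0.18 with 1 of 27 higher and 1 lower. Its higher member was the growth factor Igf1 (2.16-fold, with 0.04 at its other probe set), its lower member was Igfbp3 (2.62-fold), and the signalling genes Irs2 and Igf1r differed by -0.99 and -0.90. Interferon-stimulated genes had a median of -0.71 with 3 of 19 lower (Psmb9, Gbp3 and Irf9), epithelium markers -0.40 with 3 of 17 (Krt7, Epcam and Krt18), and adipose tissue markers -0.61 with 3 of 8 (Adipoq, Car3 and Lpl). Macrophage and dendritic cell markers had a median of -0.51 with 1 of 13 lower, Tyrobp (-1.09), and values of -0.86 for H2-Aa, -0.76 for H2-Eb1 and -0.66 for H2-Ab1, which encode class II antigen-presenting molecules. For lymphocytes and plasma cells the median was -0.43 with 2 of 7 lower, Jchain (-1.18) and Ighm (-1.05), and it lay inside the range with the mean over probe sets (-0.19).

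Several lists stayed inside the range against 0 h at all 4 times. Oestrogen-responsive uterine genes had a median of -0.03 at 9 h with 2 of 22 higher, Hspa5 and Igf1, and 3 lower, Clca1, Lifr (3.37-fold) and Ltf (3.01-fold). With the mean over a gene's probe sets the 9 h difference of Lifr was -0.35, under 2-fold, and that of Clca1 -1.11. That mean counts a probe set at the floor on both arrays as 0, so the smaller values do not by themselves show a contrary probe set. Cytokines, chemokines and prostaglandin synthesis genes had a median of -0.14 at 9 h with 0 of 17 at least 2-fold different, and values of -0.64 for Cxcl12 (-0.50 and -0.036 at its other probe sets) and -0.52 for Cx3cl1. Neutrophil markers had a median of 0.22 at 3 h, with 1 of 5 lower (Ltf), those of mast cells and eosinophils 0.28 at 1 h, with Kit at 0.62 and Hdc at 0.36, and those of ovary and oviduct 0.21 at 1 h, with 1 of 7 lower (Ovgp1) and Cyp11a1 at 0.91. Of the 30 lists, 4 were above and 7 below the range at 9 h. A pseudocount left 142 probe sets at 9 h and a 3-fold limit 63, and with the 1 h array as the baseline 176 were higher and 137 lower, which turned the balance of directions. With that baseline progesterone receptor targets had a median of 0.20, above their range, with 3 higher (Lrp2, Hdc and Acod1) and 6 lower, and the medians of clock genes (-0.21), heat shock genes (0.12), epithelium (-0.089) and lymphocytes (-0.083) at 9 h lay inside their ranges. Glucocorticoid targets (-0.39) and immediate early genes (-0.24) then lay below theirs, and cholesterol genes (0.19) above. Under other settings some of these lists came outside: oestrogen-responsive genes at 1 h with a pseudocount (0.14), cytokine genes at 6 h (-0.19) and 9 h (-0.17) with a floor at the 25th percentile, mast cells at 6 h (0.77) and 9 h (0.71) with a floor at the 55th percentile, and ovary and oviduct at 9 h with a pseudocount (-0.34). Cytokine genes at 6 h did so with the mean over probe sets too, and mast cells at 1 h without scaling (0.22). With the floor at the 55th percentile, the only mast cell list member at least 2-fold higher at 6 h and 9 h was Hdc. It is also on the list of progesterone receptor targets.

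**Figure D4:**
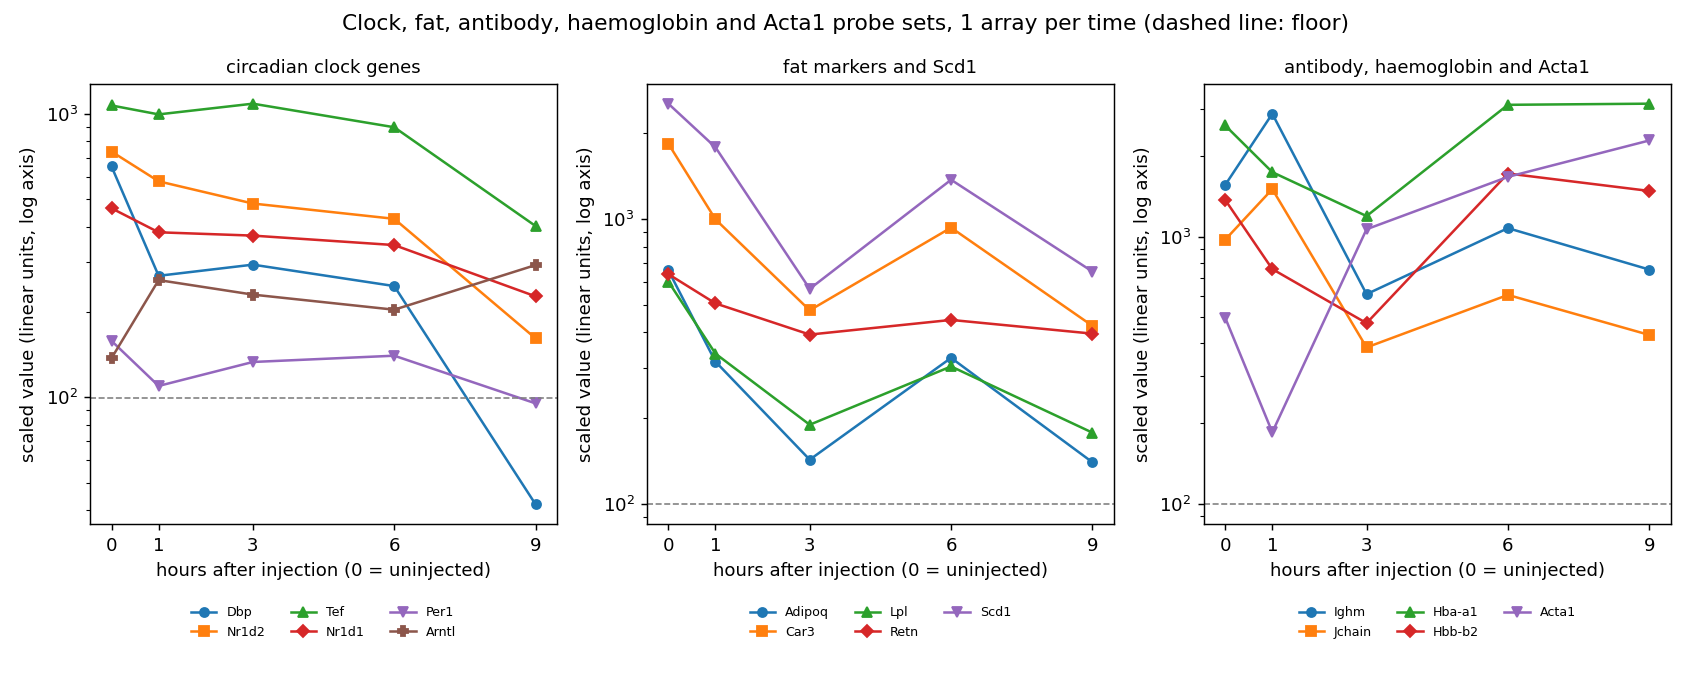
Scaled values (log axis, linear units) of clock, fat, antibody, haemoglobin and Acta1 probe sets against hours after injection, each point 1 array and the dashed line the floor of 99.5. Nr1d2 ran from 737 at 0 h to 161 at 9 h, Adipoq was 660, 316, 143, 325 and 140 at the 5 times, and Ighm was 2886 at 1 h and 609 at 3 h.

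Consecutive arrays were compared to place the differences in time. Between 1 h and 3 h, Acot7 was 9.53-fold higher, Acta1 5.76-fold and Cyp26a1 4.50-fold (121 and 545), and the antibody heavy chain genes Ighm (4.74-fold, 2886 and 609), Igha (4.30-fold, with -0.25 at its other probe set) and Ighv1-54 (-2.36) were lower, with 4 of the 7 other Ighm probe sets in the same direction. Between 3 h and 6 h the haemoglobin genes Hbb-b2 (3.63-fold, 475 and 1724) and Hba-a1 (2.61-fold) and Scd1 (2.42-fold) were higher, and Ogt, which attaches N-acetylglucosamine to proteins, was lower (2.16-fold). Between 6 h and 9 h, Pdia3, a protein folding enzyme (2.31-fold), D17H6S56E-5 (1.03) and the calcium-binding Calb1 (1.02) were higher. Napsa, an aspartic protease (3.12-fold), Cyp26a1 (2.85-fold, 473 and 166) and the methyltransferase Inmt (2.68-fold) were lower between those times.

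The first of these steps held the most probe sets past 2-fold, 88 (37 higher and 51 lower) between 1 h and 3 h, 20 (14 and 6) between 3 h and 6 h, and 37 (10 and 27) between 6 h and 9 h. The count of 20 was near the mean of 20.6 (at most 34) in simulations whose spread came from the 6 h and 9 h arrays. That spread holds any response between those times, and the step with 37 supplied it, so the simulations do not measure an absence of effect. The fold that held 95% of probe sets differed little between the steps (1.42, 1.45 and 1.41). In the first step 15 of the lower probe sets were of immunoglobulin genes, and with 1 probe set per gene 33 were higher and 30 lower. Without scaling, 20 were higher and 1 lower from 3 h to 6 h, and 15 higher and 21 lower from 6 h to 9 h. The steps span unequal times, and with a floor at the 25th percentile 37 probe sets passed between 3 h and 6 h and 59 between 6 h and 9 h. From 3 h to 6 h, 12 passed with a floor at the 55th percentile, 8 with a pseudocount and 2 at 3-fold, and from 6 h to 9 h, 20, 10 and 1.

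Probe sets were sorted by the times at which they passed. At all 4 times 3 probe sets were at least 2-fold higher, for Sgk1, Zbtb16 (1 of its probe sets) and the glucose transporter gene Slc2a3 (1 of its probe sets, with 0.87 at 1 h at its main probe set), and 9 were lower, including Adipoq, Dbp and Efnb2. At 3 h, 6 h and 9 h together 33 were higher, including Acot7, Lrp2, Ihh and Hdc, and 42 were lower, including Tgfbi, Igfbp3, Lifr and Slc15a2. At 1 h or 3 h, with under 1.5-fold in the same direction at 6 h and 9 h, 27 were higher, including Esr1 and Gadd45g, and 15 were lower, including Elf3, Ier3 and Hbb-b2. These groups also held genes that differed the other way at 9 h, including Bcl6 (-0.64), Ighv1-54 (at least 1.54 lower) and Igkv9-120 (at least 1.17 lower) among the higher and Acta1 (2.20) among the lower, and a limit in either direction left 37 of the 42. At 6 h and 9 h, with under 1.5-fold in the same direction at 1 h and 3 h, 11 were higher, including Hspa5 and Dnajc3, both of protein folding in the endoplasmic reticulum, and 3 were lower, for Rin2, Sash1 and Lox, which crosslinks collagen.

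The 3 h and 6 h differences shared 45 higher and 52 lower probe sets, and those at 6 h and 9 h shared 63 and 55. Because every difference from 0 h uses the same array, some overlap arises with no effect: simulated sharing at 3 h and 6 h averaged 4.09 higher and 0.43 lower probe sets, and the highest counts in 100 simulations were 11 and 3. The 1 h differences shared 10, 9 and 5 higher probe sets with those at 3 h, 6 h and 9 h, against simulated highest counts of 12, 10 and 10. They shared 17, 10 and 14 lower ones, against 3, 2 and 3. The simulated differences kept the sign of 9 h minus 6 h, a step with 10 probe sets higher and 27 lower. Simulated counts differed by direction, so which direction exceeded no effect at 1 h cannot be told from them. The correlation of the 1 h differences with the 3 h differences was 0.721, above that simulated with no effect. With the 6 h differences it was 0.443, below the 0.501 simulated, and with the 9 h differences lower still, 0.288, although the covariances, 0.0368 and 0.0263, exceeded the simulated 0.0222 and 0.0221. At all 4 times there were 3 higher probe sets, with a simulated mean of 2.11 and at most 9. There were 9 lower ones, with a simulated mean of 0.03 and at most 1. The simulated counts again differed by direction, so the directions were not judged against them. Both directions together gave 12, above the simulated mean of 2.14 and highest of 9. The simulated spread came from the 6 h and 9 h arrays, the pair most alike. The standard deviation of their log2 differences was 0.211, against 0.271 to 0.341 between 0 h and the other arrays, which also hold any response. If the 0 h pool or array varied more than that pair, the simulated overlaps, correlations and covariances are too low. The total of 12 was 19 without scaling, 20 and 6 with floors at the 25th and 55th percentiles, and 1 with a pseudocount or a 3-fold limit. The single control array cannot be divided, so how much of the overlap comes from it was not measured.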

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

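The tests of explanations in this part were chosen after the results were seen.

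A total of 3 probe sets were at least 2-fold different from 0 h in opposite directions at different times, each with 1 array per time, and the difference between the times was not tested. Acta1, skeletal muscle actin, was -1.43 at 1 h and 1.10, 1.75 and 2.20 at 3 h, 6 h and 9 h. The antibody light chain probe set for Igkv9-120 was 1.45 at 1 h and at least 1.17 lower (-1.17) at both 3 h and 9 h, where it lay at the floor. The antibody heavy chain probe set for Ighv1-54 was 1.03 at 1 h, -1.33 at 3 h and at least 1.54 lower (-1.54) at 9 h, where it lay at the floor.

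The antibody genes and the fat markers differed between pools in no steady order of time. Of 26 immunoglobulin probe sets at 2 times the floor or more on some array, 23 (88.5%) were lower at 3 h than at 1 h, with a median of -1.14, against 49.2% of all probe sets at that level. These values restate the pattern in its own genes, so they do not decide for or against different numbers of antibody-secreting cells in the pools. For different amounts of attached fat in the pools, 5 of 8 adipose markers were lower than at 0 h at all 4 times. The differences of Adipoq, Car3 and Lpl lay within 0.22, 0.54, 0.04 and 0.48 of one another at 1 h, 3 h, 6 h and 9 h, but these genes define the pattern. Fabp4, an abundant fat transcript, was at 64.8 at 0 h, under the floor of 99.5, so the test did not decide. An effect of the hormone or of time on those cells cannot be told apart from either, because 0 later arrays came from uninjected mice.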

How the results depend on the processing

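The settings with the 1 h array as the baseline and with a 1.5-fold limit in either direction were chosen after the data were seen, and all others before the data were examined. No paired analysis was possible because each time had 1 pooled sample, and for the same reason no array could be left out in turn. Of 211 named differences, 126 were at least 2-fold, and all 126 kept their direction under the 7 other settings of scaling, floor, pseudocount and averaging. A floor or a pseudocount cannot reverse the order of 2 values, and the scalings moved a named difference by at most 0.18. Only the mean over probe sets could therefore have turned a direction. Of the 126, 125 stayed at least 2-fold with median centring, 122 with quantile normalization and 121 without scaling. All 126 did so with the floor at the 25th percentile, but a lower floor can only keep or widen a difference, so that count was fixed in advance. With the floor at the 55th percentile 113 did so, with the mean over probe sets 106 and with a pseudocount 102. The mean over probe sets counts a probe set at the floor on both arrays as 0, which can shrink a difference or a list median without a contrary value. Of the 211, 35 moved by 1.5-fold or more with the floor at the 55th percentile, 25 with the mean over probe sets, 19 with a pseudocount, 10 with the floor at the 25th percentile and 0 under the 3 scalings. Dropping the minimum on the higher value could not alter a count, because a 2-fold difference above the floor already reaches 2 times the floor. Values near the floor, where 4209 probe sets lay on all arrays, carry no measurable difference. Of 46 list medians outside their random range, 31 stayed outside it under all 7 of those settings. Each list median given below lay inside its random range under the setting named, which ended the call, except the glucocorticoid median at 3 h against 1 h, which lay below its range. Of 74 list medians inside their range, 16 lay outside it under at least 1 of the 7 settings. Those outside under 3 or more were immediate early genes at 6 h and 9 h, and cholesterol genes at 3 h and at 9 h. Where no reason is given below, the cause was not tested.

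A pseudocount equal to the floor, which shrinks every fold by construction, gave 18 probe sets at 1 h, 103 at 3 h, 87 at 6 h and 142 at 9 h, and 51, 8 and 10 for 3 h against 1 h, 6 h against 3 h and 9 h against 6 h. It gave 1 probe set at all 4 times, 10 at 1 h or 3 h only and 7 at 6 h and 9 h only, and medians of 0.11 for immediate early genes at 1 h and 0.16 for steroid receptors and cofactors at 3 h. A 3-fold limit, stricter by construction, gave 6, 46, 34 and 63 probe sets at the 4 times, 30, 2 and 1 for the consecutive steps, 1 at all 4 times, 1 at 1 h or 3 h only and 0 at 6 h and 9 h only. With 1 probe set per gene, fewer probe sets entered, and 41 passed at 1 h and 13 for 6 h against 3 h.

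The floor at the 25th percentile gave 37 probe sets for 6 h against 3 h, 59 for 9 h against 6 h, 20 at all 4 times and 65 at 1 h or 3 h only. Its list medians were 0.11 for immediate early genes at 1 h, 0.13 for glucocorticoid targets at 6 h, 0.13 and 0.18 for steroid receptors at 3 h and 6 h, 0.15 for ribosomal proteins at 1 h, -0.10 and -0.034 for lymphocytes and plasma cells at 3 h and 6 h, and 0.36 for skeletal muscle at 3 h. The floor at the 55th percentile gave 36 probe sets at 1 h, 12 for 6 h against 3 h, 20 for 9 h against 6 h, 6 at all 4 times and 23 at 1 h or 3 h only. Its medians were 0.11 for immediate early genes at 1 h, 0.19 and 0.21 for steroid receptors at 3 h and 6 h, and 0.29 for smooth muscle at 9 h.

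The 1.5-fold limit in either direction gave 37 probe sets at 1 h or 3 h and 14 at 6 h and 9 h. Values without scaling gave 19 probe sets at all 4 times. Quantile normalization gave medians of 0.12 for immediate early genes at 1 h, 0.16 for glucocorticoid targets at 3 h, 0.14 for steroid receptors at 3 h, 0.0021 for ribosomal proteins at 1 h and -0.18 for macrophages and dendritic cells at 6 h. The mean over the probe sets of a gene gave 0.11 for immediate early genes at 1 h, 0.19 for endoplasmic reticulum chaperones at 3 h, 0.15 and 0.16 for steroid receptors at 3 h and 6 h, 0.10 for stroma at 1 h, -0.20 and -0.10 for macrophages at 3 h and 6 h, -0.18, -0.13 and -0.19 for lymphocytes at 3 h, 6 h and 9 h, and 0.24 for skeletal muscle at 3 h.

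With the 1 h array as the baseline, 88 probe sets passed at 3 h. The glucocorticoid median reversed to -0.14 at both 3 h and 6 h, and that of macrophages and dendritic cells reversed to 0.057 at 6 h. Other medians that moved were 0.078 for endoplasmic reticulum chaperones, 0.030 for steroid receptors, 0.021 for stroma, -0.035 for macrophages and -0.11 for lymphocytes at 3 h, and 0.022 for heat shock genes, 0.065 for steroid receptors, -0.15 for interferon-stimulated genes, -0.14 for epithelium, -0.20 for lymphocytes and -0.039 for adipose tissue at 6 h. At 9 h they were -0.21 for clock genes, 0.12 for heat shock genes, -0.089 for epithelium and -0.083 for lymphocytes. Of the probe sets called against 0 h, 28 of 76 higher and 37 of 132 lower were also called against 1 h at 3 h, 57 of 94 and 22 of 78 at 6 h, and 86 of 126 and 68 of 147 at 9 h.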

Other observations

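The tests of explanations in this part were chosen after the results were seen.

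Haemoglobin transcripts followed neither a rise nor a fall with time. Hba-a1 was at 2609 at 0 h, 1744 at 1 h, 1195 at 3 h, 3118 at 6 h and 3149 at 9 h, and Hbb-b2 at 1374, 756, 475, 1724 and 1484. Among markers of the other tissues near the uterus, Ovgp1, made chiefly by the oviduct, was at 753, 218, 194, 393 and 196 over the same times. Hdc, which makes histamine and is also expressed by mast cells, was at 744, 953, 2257, 2516 and 2254, while the mast cell proteases Cma1 and Cpa3 differed from 0 h by -0.20 and by at least 0.28 at 1 h, by -0.096 and at least 0.24 at 3 h, and at 6 h Cma1 was at least 0.38 lower and Cpa3 at least 0.11 higher. At 9 h Cma1 differed by -0.25 and Cpa3 was under the floor, as at 0 h.

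Of the 65 control probe sets, 0 passed the 2-fold rule. The 7 probe sets for the bacterial spike-in transcripts BioB, BioC and BioDn were all lower than at 0 h at each time, with medians of -0.18, -0.28, -0.41 and -0.54 at 1 h, 3 h, 6 h and 9 h, and the 2 Cre probe sets had medians of 0.17, 0.29, 0.08 and 0.04. The control probe set for the transferrin receptor, which takes up iron, was at 54.7, 94.3, 118, 129 and 158 from 0 h to 9 h, with the floor at 99.5.

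The lists of interferon-stimulated genes and epithelium markers had medians below their random ranges at every time. An uninjected pool that alone stood apart was tested with the 1 h array as the baseline, under 7 other settings of scaling, floor, pseudocount and averaging as well. At 3 h the interferon median was then -0.16 (members from -0.59 to 0.51) and the epithelium median -0.12 (members from -0.90 to 0.89). The random ranges ended at -0.11 for both, and each median was below its range under all 7. Those settings use the same 2 arrays again. With that baseline 7 lists stayed outside on the same side at 3 h and 5 more came outside, where 1.5 were expected. A difference between the 1 h and 3 h pools could give such values, so the test could not decide at 3 h. At 6 h they were -0.15 and -0.14, inside their ranges. At 9 h the interferon median was -0.37, below its range, but inside it with a floor at the 55th percentile (-0.27) and with the mean over probe sets (-0.22). The epithelium median was -0.089, inside its range, with members from -0.58 to 1.16. An uninjected pool that alone stood apart thus stays open at 3 h, 6 h and 9 h. A smaller share of epithelium in the 9 h pool would lower its markers by about 1 common fold. The highest and lowest markers at 9 h were 1.89 apart, within the 0.80 to 3.31 that held the central 95% of matched random lists, and 4 of 17 were higher than at 0 h, so that share stays open too. An effect of the hormone or of time on those genes stays open, because 0 later arrays came from uninjected mice.

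The clock genes at 9 h lay on both sides of 0. The median of Dbp, Tef, Nr1d1 and Nr1d2 was -1.80 and Arntl was 1.09, both beyond the 0.84 within which 95% of probe sets lay between those arrays, while Per3 was 0.29, Cry1 0.31, Npas2 -0.20 and Per2 at least 0.18 lower, with 9 h at the floor. At 1 h Dbp was already at -1.28 and Arntl at 0.92. These values restate the pattern, and the labels give no hour of collection, so time of day at collection and an effect of the hormone on the clock cannot be told apart, because 0 later arrays came from uninjected mice.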
